A study of Homo sapiens with 12 samples.

How the data were processed

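RNA from 2 human lung adenocarcinoma cell lines, H1975 and PC-9, was measured on a whole-transcript oligonucleotide array with 1 colour. The 12 arrays form 4 groups of 3. In each line, 1 group holds osimertinib-tolerant cells, which per the labels survived 0.5 µM osimertinib for 1 week and were collected at day 8. The other group holds such cells after 48 h with 100 µM SK-216, a compound known here by its code name. Osimertinib is an inhibitor of the epidermal growth factor receptor, and 250 ng of RNA was used per array, per the labels' protocols.

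The values are log2 signals as deposited by the authors, with 1 value per probe set and array. Transcriptome Analysis Console is named per the submitters' processing notes, and its version, the summarisation and the normalization method are not given in the sources used here. The deposited log2 values ran from 2.19 to 18.61, and the array medians lay between 6.56 and 6.62. No further normalization was applied. Arrays give no read depth, so their number, 3 per group, limits the precision.

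Of 21448 probe sets, 17709 had 1 gene symbol, none had several, and 3739 were unnamed here. Names came from the platform annotation and were looked up by Entrez identifier in a RefSeq gene table of assembly GRCh38.p14, in which all 17709 identifiers were found. The build behind the array is not given in the sources used here, so no coordinates are printed. The named probe sets carried 17687 symbols, 20 of them on more than 1 probe set, and 78 probe sets had 12 values identical to those of another. Probe sets were tested separately and none was filtered out. A planned result for a single gene is not reported here.

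A linear model with 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with eBayes and a trend of the variance on mean level. The fit had 8 residual degrees of freedom and a median of 15.0 prior degrees of freedom. The contrasts were SK-216 against tolerant cells in each line, the difference of these changes (PC-9 minus H1975), and tolerant PC-9 against tolerant H1975 cells. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all probe sets, and an adjusted p below 0.05 counted as a call. Changes are given as log2 fold change ± standard error of the fit, with 3 arrays per group, unless a standard deviation is named. Nothing in the labels says that replicates came from separate cultures, so p-values of probe sets measure only the spread between these arrays, which may be technical.

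Before the data were examined, 42 gene lists with 1057 distinct genes were fixed, of which 935 were measured. Each list was tested with limma's camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry, whose p tests whether the genes of a list move on balance in 1 direction. Camera sets the genes of a list against all other genes. Its p-values therefore depend on the number of genes and on the correlation taken, and not only on the spread between arrays. Adjusted p-values of lists are over the 42 lists of a contrast. The rule for named genes was fixed at the same time. For SK-216 in each line it took the 10 largest increases and 10 largest decreases among genes with a call and no overlap between the 3 arrays of each group. It also took up to 4 members with the smallest adjusted p of each list that passed or held at least 3 calls, 5 genes per direction for the difference, for the lines and for both lines together, and EGFR, PLAU, PLAUR, VIM, CDH1, MKI67 and CCNB1. Olfactory receptor probe sets, chosen after the data were examined, served to describe the level of unexpressed genes: the 349 had a median of 3.61 and a 95th percentile of 5.05 on the log2 scale.

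The fit was tested on simulated data made from the real line means of all 21448 probe sets and their variances after eBayes with the trend. For SK-216 in H1975, 22.7% of planted changes of 0.5, 88.1% of changes of 1 and 100% of changes of 2 on the log2 scale were recovered, with 9 false calls among 21229 unchanged probe sets. For SK-216 in PC-9 the shares were 32.8%, 85.1% and 100%, with 8 false calls among 21248. The simulated noise was normal and independent between genes, with variances from the same eBayes fit. It therefore tests neither the preset correlation nor the variance trend.

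Alternatives fixed before the data were examined were eBayes without a trend, robust eBayes, each line fitted alone, the replicate number as a block within each line or over both, leaving out the dimmest 30% of probe sets, quantile normalization, centring arrays on their medians, array weights, stricter thresholds, 1 probe set per symbol, other set tests, and leaving out each of the 12 arrays. Another 3 were added after the data were examined: leaving out probe sets at olfactory receptor levels, leaving out the array of each line farthest from its group, and leaving out unnamed probe sets beside repeated symbols. Figures were drawn with matplotlib.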

Results

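The series asked what 48 h with SK-216 changed in lung cancer cells that had survived osimertinib. H1975 and PC-9 are adenocarcinoma lines that carry activating mutations of the epidermal growth factor receptor. Each line gave 3 arrays of tolerant cells and 3 arrays of tolerant cells after SK-216. Arrays of a group correlated at r between 0.993 and 0.995 across probe sets, and arrays of different lines at r between 0.927 and 0.932. SK-216 and tolerant arrays of the same line correlated at r between 0.9919 and 0.9933 in H1975 and between 0.9923 and 0.9943 in PC-9. The PC-9 range overlaps that of arrays of a group. The sources disagree on 1 point: the source name of the SK-216 samples calls the starting cells naive, while their titles, descriptions and treatment texts call them tolerant. The labels do not say whether osimertinib was kept during SK-216, and no tolerant cells collected 48 h later without it are described, so SK-216 and the added time are compared together.

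In H1975 cells, genes of the interferon response fell after SK-216. Of 43 measured members, 32 fell and 0 rose, with a median log2 fold change of -0.93 (camera adjusted p = 5.99e-47; adjusted p = 0.000111 with an estimated correlation), and 39 fell when p-values were adjusted over the list alone. MX1, an antiviral GTPase, fell from 13.09 ± 0.23 to 11.30 ± 0.21 (mean log2 signal ± SD, n = 3), a change of -1.79 ± 0.13. IFIT1, which binds viral RNA, changed by -2.01 ± 0.22 and IFIT3 by -1.75 ± 0.16. The largest decrease among genes named by the rule was that of TNFSF10, the death ligand TRAIL, at -3.54 ± 0.19 (adjusted p = 1.31e-11). Genes of antigen presentation fell too, 4 of 18 by the test over all genes and 10 adjusted over the list alone (camera adjusted p = 4.35e-06), among them HLA-E at -0.62 ± 0.13 and TAPBP, which loads peptides on class I molecules, at -0.46 ± 0.10.

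Genes of the ATF4 and amino acid response rose in H1975. Of 37 measured genes on 38 probe sets, 25 probe sets rose and 1 fell, 28 and 1 adjusted over the list alone (median 0.56, camera adjusted p = 2.85e-24). SLC7A11, the cystine transporter, rose by 1.70 ± 0.09, ATF3, a stress-induced transcription factor, by 1.48 ± 0.17, and ASNS, asparagine synthetase, by 0.85 ± 0.12. Endoplasmic reticulum chaperone and stress genes rose for 8 of 26 members, 12 adjusted over the list alone (camera adjusted p = 2.57e-07), with HERPUD1 at 0.84 ± 0.09 and DNAJB9 at 0.85 ± 0.11. In the hypoxia list 9 of 23 rose, 14 adjusted over the list alone, with 1 fall (camera adjusted p = 1.94e-09), including NDRG1 at 0.94 ± 0.13, VEGFA, the vascular growth factor, at 0.62 ± 0.10, and SLC2A1, the glucose transporter, at 0.53 ± 0.08. Cholesterol synthesis genes rose for 7 of 20, 8 adjusted over the list alone, with 1 fall (camera adjusted p = 4.35e-06), with MSMO1 at 0.81 ± 0.09 and DHCR7 at 0.71 ± 0.10. Of the ERK pathway output genes 7 of 23 rose, 9 adjusted over the list alone, with 1 fall (camera adjusted p = 1.48e-05), among them FOSL1 at 1.67 ± 0.16, ETV5 at 1.03 ± 0.14 and CCND1, cyclin D1, at 0.79 ± 0.11.

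The other large increases in H1975 were those of ANGPTL4, a secreted inhibitor of lipoprotein lipase, at 2.74 ± 0.21, LBH at 2.37 ± 0.18, DUSP15, a phosphatase, at 2.10 ± 0.24, RCAN1, a calcineurin regulator, at 2.09 ± 0.13, STK32A at 2.09 ± 0.31, AGR2, a protein disulfide isomerase, at 2.01 ± 0.25, IGFBP3, which binds insulin-like growth factors, at 1.96 ± 0.09, and ATP6V0D2, a proton pump subunit, at 1.79 ± 0.23. AGR2, STK32A and ATP6V0D2 started at 3.38 ± 0.28, 4.20 ± 0.77 and 4.88 ± 0.27 (mean log2 signal ± SD), within the range of olfactory receptor probe sets. Large decreases were also measured for ACP3, a phosphatase, at -3.02 ± 0.29, STEAP4, a metalloreductase, at -2.49 ± 0.14, MGP, matrix Gla protein, at -2.40 ± 0.25, S100A9, a subunit of calprotectin, at -2.38 ± 0.19, BMP4, a growth factor, at -2.11 ± 0.26, and NFE2, a transcription factor, at -2.10 ± 0.21. NFE2 ended at 3.93 ± 0.32 and ACP3 at 5.03 ± 0.24 with SK-216 (mean log2 signal ± SD), within that range. SERPINB4 at -2.29 ± 0.19 and SERPINB3 at -2.17 ± 0.26 are near-identical paralogs, and their probe sets may share signal. CDH1, the epithelial cadherin, fell, with a change of -1.55 ± 0.13 (adjusted p = 4.51e-08), while EPCAM, another epithelial adhesion molecule, rose by 0.77 ± 0.13. The epithelial list had 5 rises and 4 falls among 23 genes, 9 and 6 adjusted over the list alone, and did not pass (camera adjusted p = 0.533). PLAU, the urokinase that activates plasminogen, changed by -0.65 ± 0.12 (adjusted p = 0.00223), and the plasminogen activation list did not pass (camera adjusted p = 0.285). That list had 4 falls and 1 rise among 15 genes, 5 and 1 adjusted over the list alone, and fry called it lower (fry adjusted p = 0.0132). VIM, an intermediate filament of mesenchymal cells, was at 0.01 ± 0.14, PLAUR, the urokinase receptor, at -0.02 ± 0.15, MKI67, a proliferation marker, at 0.04 ± 0.15, and CCNB1, cyclin B1, at -0.15 ± 0.13, none past the test. EGFR, the target of osimertinib, rose by 0.52 ± 0.12 (adjusted p = 0.0141), a call that ended without 1 array in 2 of the 12 fits that left out an array (highest adjusted p = 0.0939).

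Lists that passed in H1975 and held with an estimated correlation also included TGF-beta targets and ribosome biogenesis and MYC targets. TGF-beta targets were lower, with a mean shift of -0.25 against all probe sets (camera adjusted p = 0.00178, and 0.0472 with an estimated correlation). Ribosome biogenesis and MYC targets were higher by 0.15 (camera adjusted p = 0.00746, and 0.0457 with an estimated correlation). Both values with an estimated correlation, and that of ERK pathway output (0.042), lay close to the threshold. The TGF-beta list had 4 falls, such as SMAD6, an inhibitory SMAD, at -1.31 ± 0.27, and 1 rise, with 8 and 1 adjusted over the list alone. The remaining calls were lost with an estimated correlation. NF-kB and cytokine genes, 10 lower and 2 higher, had adjusted p = 0.057 with an estimated correlation, with SAA1, an acute phase protein, at -1.48 ± 0.11, CXCL1, a chemokine, at -1.28 ± 0.20, and LCN2, lipocalin 2, at 0.79 ± 0.12. PPAR targets had adjusted p = 0.0524 with an estimated correlation, with PLIN2, a lipid droplet protein, at 1.58 ± 0.21 and CPT1A, which imports fatty acids into mitochondria, at 1.15 ± 0.16. AhR targets had adjusted p = 0.057 with an estimated correlation, with TIPARP at 0.84 ± 0.09 and CYP1A1 at 1.29 ± 0.25. Oxidative phosphorylation, lower by a mean of -0.17, had adjusted p = 0.37 with an estimated correlation. The same was true of mesenchymal markers (adjusted p = 0.0761 with an estimated correlation), extracellular matrix (0.0968), integrins and focal adhesion (0.418), G1/S and DNA replication (0.0986), p53 targets (0.154), immediate early genes (0.367), receptor tyrosine kinases and ligands (0.309), and squamous and neuroendocrine markers (0.258). Each of these 8 calls also ended in 2 to 8 of the 12 fits that left out 1 array. In these lists FN1, fibronectin, changed by -0.72 ± 0.12, SPARC, a matrix protein, by -0.58 ± 0.08, ITGB1, an integrin chain, by -0.36 ± 0.07, and GADD45A, a growth arrest gene, by 0.72 ± 0.14. Markers of leukocytes, endothelium and fibroblasts did not pass (camera adjusted p = 0.752, 0.999 and 0.326).

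In all, 814 probe sets passed in H1975, 309 higher and 505 lower, and 154 of them changed by at least 1 on the log2 scale. At an unadjusted p below 0.05 there were 3045, and in 18.5% of probe sets the arrays of both groups did not overlap, against 10% by chance. Without the variance trend 448 passed. Of the 42 lists 21 passed, 13 higher and 8 lower, and 9 passed with an estimated correlation.

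**Figure D1:**
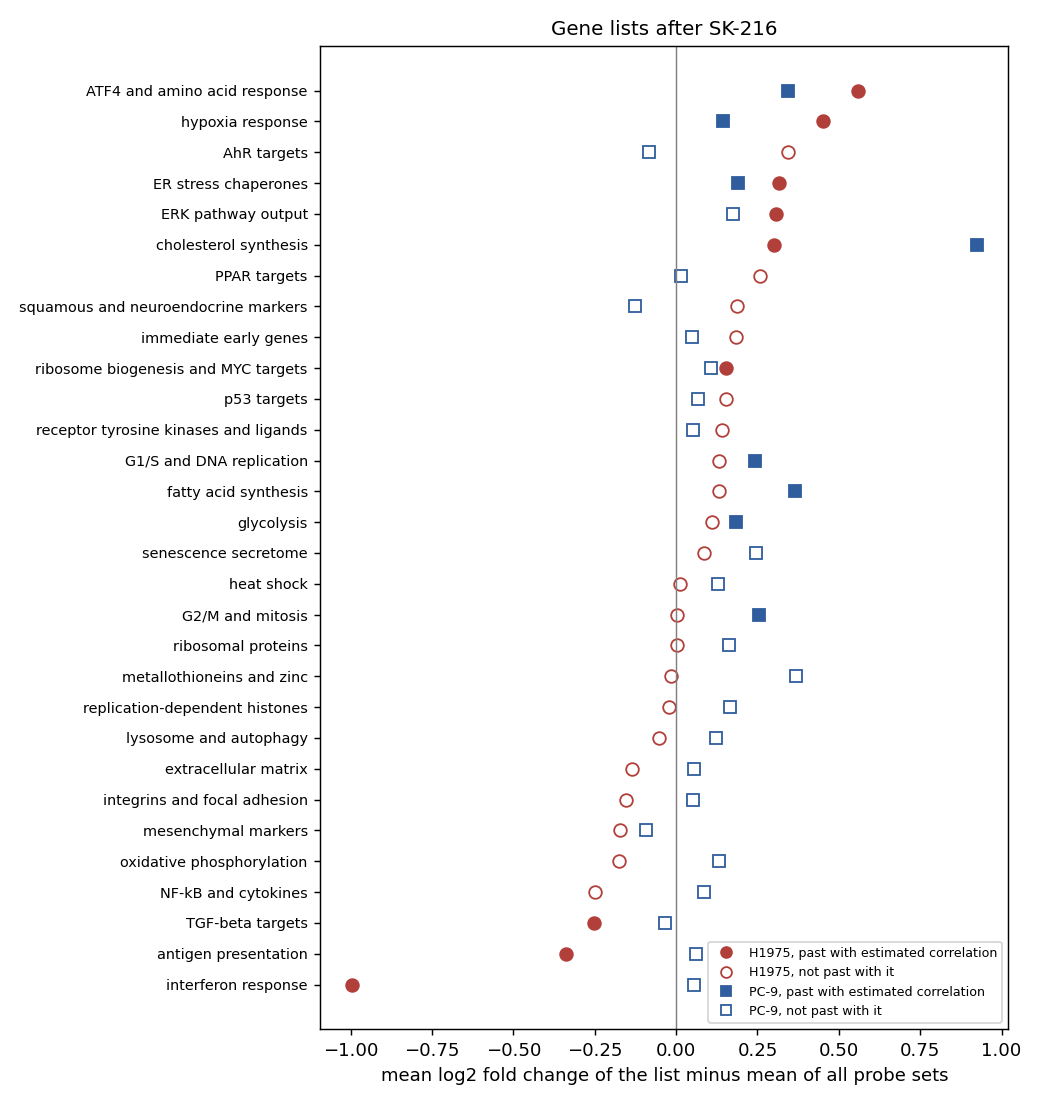
Mean log2 fold change of each list that passed in at least 1 line, minus the mean of all probe sets (x axis), for H1975 (circles) and PC-9 (squares). Filled symbols passed with an estimated correlation, open ones did not, and the interferon list lies farthest to the left in H1975 while the cholesterol list lies farthest to the right in PC-9 at 0.92.

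In PC-9 cells, cholesterol synthesis genes rose after SK-216. Of 20 measured members 14 rose and 0 fell, 18 adjusted over the list alone, with a median log2 fold change of 0.95 (camera adjusted p = 1.62e-36; adjusted p = 0.000163 with an estimated correlation). HMGCS1, which makes HMG-CoA, rose from 13.01 ± 0.07 to 14.32 ± 0.04 (mean log2 signal ± SD, n = 3), a change of 1.31 ± 0.10. ACAT2 rose by 1.46 ± 0.15, MVD, mevalonate diphosphate decarboxylase, by 1.41 ± 0.20, IDI1, isopentenyl diphosphate isomerase, by 1.35 ± 0.17, CYP51A1, lanosterol demethylase, by 1.31 ± 0.10, SQLE, squalene epoxidase, by 1.20 ± 0.16, and FDPS, farnesyl diphosphate synthase, by 1.17 ± 0.12. The largest increase was that of SCD, stearoyl-CoA desaturase, at 2.32 ± 0.16 (adjusted p = 1.61e-08), in a fatty acid synthesis list where 4 of 15 rose, 6 adjusted over the list alone (camera adjusted p = 1.61e-05). FADS2, a fatty acid desaturase, rose by 0.71 ± 0.11 and TMEM97, a regulator of cholesterol transport, by 0.86 ± 0.10.

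ATF4 and amino acid response genes rose in PC-9 on 8 of 38 probe sets, 20 adjusted over the list alone (camera adjusted p = 1.08e-15), with ASNS at 0.78 ± 0.12, PSAT1, an enzyme of serine synthesis, at 0.56 ± 0.09 and TRIB3, a pseudokinase, at 0.96 ± 0.18. The G2/M and mitosis list passed with a median of 0.26 over 40 genes (camera adjusted p = 3.11e-11), where 2 genes rose by the test over all genes and 14 adjusted over the list alone. They were AURKA, a mitotic kinase, at 0.48 ± 0.10 and CCNA2, cyclin A2, at 0.42 ± 0.09, and these calls ended in 4 and 7 of the 12 fits that left out 1 array (highest adjusted p = 0.127 and 0.188). The G1/S and DNA replication list passed with a median of 0.21 (camera adjusted p = 8.71e-08), with 1 rise, 9 adjusted over the list alone. MKI67 was at -0.04 ± 0.15 and CCNB1 at 0.43 ± 0.13, neither past the test. Hypoxia genes passed with a median of 0.10 (camera adjusted p = 0.00426), with 3 rises among 23, such as NDRG1 at 0.92 ± 0.13. Adjusted over the list alone 5 rose and 1 fell. Glycolysis passed with a median of 0.12 (camera adjusted p = 0.00112). Of its 19 members 1 rose, SLC2A3, a glucose transporter, at 0.87 ± 0.15, and 2 adjusted over the list alone. With quantile normalization both lists had camera adjusted p = 0.034. Endoplasmic reticulum chaperones passed too (camera adjusted p = 5.29e-05). None of their members passed the test over all genes, and 5 rose adjusted over the list alone.

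Calls of other lists in PC-9 were lost with an estimated correlation. Metallothioneins, metal-binding proteins of near-identical sequence whose probe sets may share signal, rose for 4 of 11 members, such as MT1H at 0.91 ± 0.15, with adjusted p = 0.114 with an estimated correlation. The senescence secretome list had 2 rises, among them CXCL8, interleukin 8, at 0.76 ± 0.13 (adjusted p = 0.0545 in the 1 leave-one-out fit that ended its call), and adjusted p = 0.101 with an estimated correlation. Adjusted p with an estimated correlation was 0.419 for ribosomal proteins, 0.373 for histones, 0.443 for oxidative phosphorylation, 0.136 for ERK pathway output, 0.24 for lysosome and autophagy, 0.101 for ribosome biogenesis and MYC targets, and 0.371 for heat shock. These lists shifted by small amounts, such as 0.11 for ribosome biogenesis and 0.17 for histones, while the dim olfactory receptor probe sets had a median change of -0.08. With quantile normalization the calls of heat shock (adjusted p = 0.256), lysosome and autophagy (0.103) and ribosome biogenesis (0.204) were lost, and over all their alternatives the adjusted p ran from 0.0243 to 0.371, 0.00443 to 0.24 and 0.000897 to 0.204. Fits that left out 1 array ended the calls of heat shock in 5 of 12, of ribosome biogenesis in 4, and of ERK pathway output, lysosome and autophagy, and oxidative phosphorylation in 1 each. The interferon list did not pass in PC-9, with a median of 0.02 (camera adjusted p = 0.339), MX1 at -0.02 ± 0.13 and IFIT1, within the range of olfactory receptor probe sets, at 0.33 ± 0.22.

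Decreases in PC-9 were few. CYP1B1, a cytochrome P450, fell, at -0.54 ± 0.08 (adjusted p = 0.0015) and kept its call in all 12 fits that left out 1 array, but not without the variance trend (adjusted p = 0.197), where all 18 calls in PC-9 were increases. SNAI2, a transcription factor of the mesenchymal state, fell, at -0.58 ± 0.11, and lost its call in 1 of them (adjusted p = 0.0849). The calls of SLC34A2, a phosphate transporter, at -1.19 ± 0.25, CT45A1, of a family of near-identical copies, at -1.08 ± 0.21, HAP1 at -0.80 ± 0.18, CRISPLD2 at -0.77 ± 0.16, STXBP4 at -0.74 ± 0.16, MAPRE2 at -0.60 ± 0.14 and GALC, galactosylceramidase, at -0.58 ± 0.13 each ended in at least 3 of those fits, with highest adjusted p of 0.15, 0.108, 0.309, 0.145, 0.15, 0.212 and 0.221. OR13C4, an olfactory receptor gene, was at -0.88 ± 0.19, from a level within the range of such probe sets, and lost its call in 6 of those fits (highest adjusted p = 0.148). CT45A1 and, with SK-216, SLC34A2 lay within that range too, as PRR16 did before SK-216. Among the increases, PRR16 at 1.12 ± 0.23 and MFAP5 at 1.10 ± 0.23 lost their calls in 5 and 4 of such fits (highest adjusted p = 0.109 and 0.153). EGFR was at 0.10 ± 0.12, PLAU at 0.07 ± 0.12, PLAUR at 0.33 ± 0.15, VIM at 0.21 ± 0.14 and CDH1 at 0.20 ± 0.13, none past the test.

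In PC-9, 95 probe sets passed, 80 higher and 15 lower, of which 21 changed by at least 1 on the log2 scale, and 2342 had an unadjusted p below 0.05. The arrays of both groups did not overlap in 15.0% of probe sets, against 10% by chance. The count fell when any array of PC-9 was left out, which also leaves fewer arrays. It was 30 without SK-216 array 2, and 60 and 59 without SK-216 arrays 1 and 3. Without tolerant arrays 1, 2 and 3 it was 66, 76 and 46. It was 18 without the variance trend, and with quantile normalization 69, of which 51 were higher and 18 lower. Of the 42 lists 17 passed, all of them higher, and 8 passed with an estimated correlation. With quantile normalization 14 of 15 were higher, without tolerant array 3 also 14 of 15, and without SK-216 array 3 15 of 16, the other list being lower each time.

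**Figure D2:**
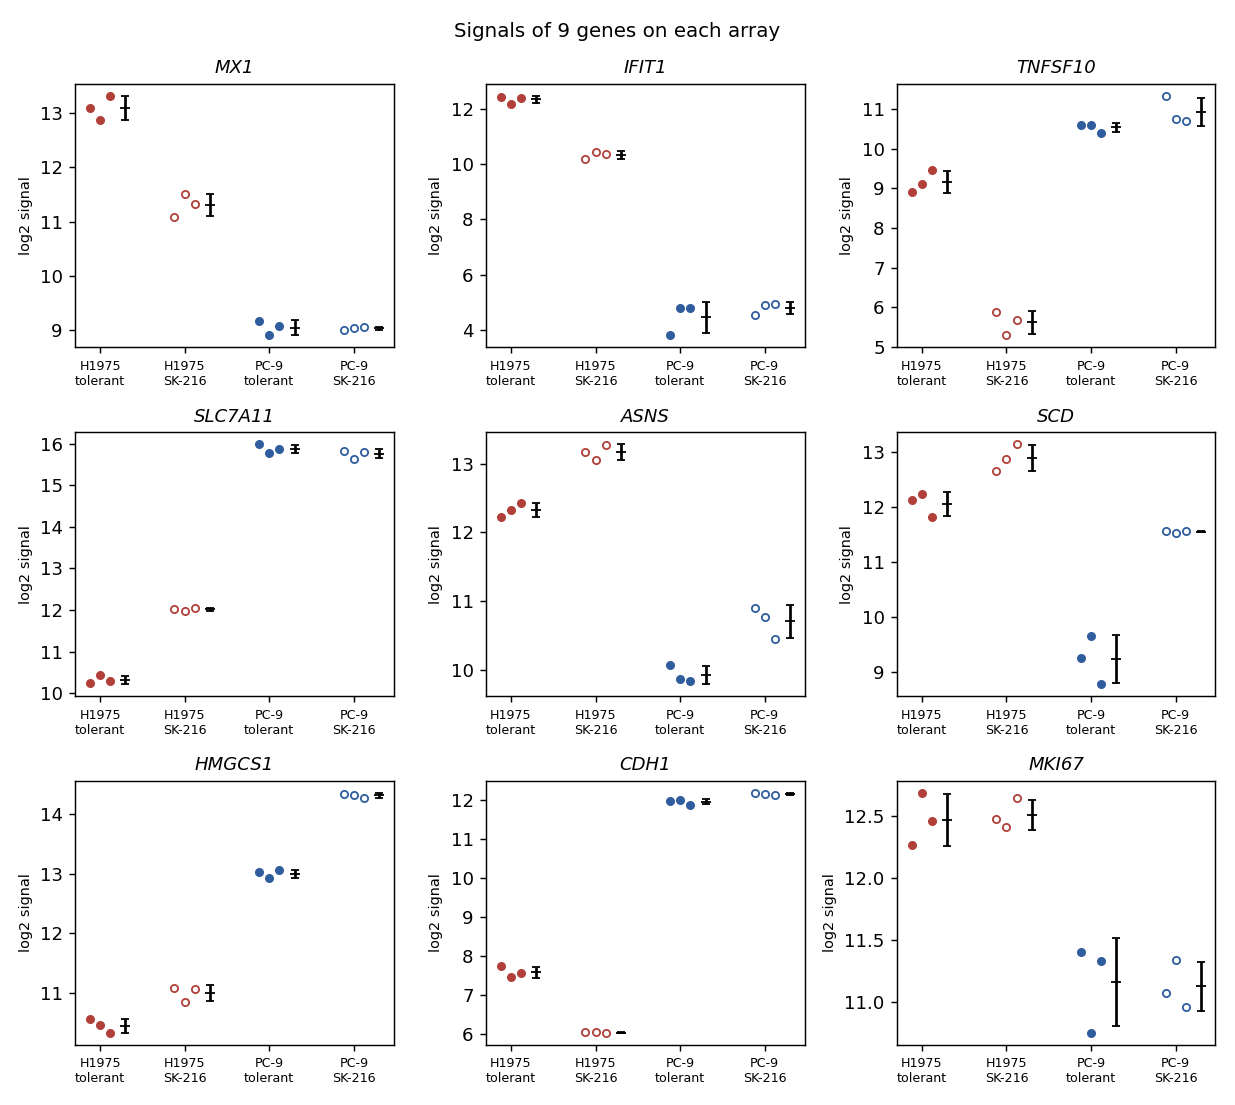
Log2 signal of 9 genes (y axis) on each of the 12 arrays, by group (x axis), with filled points for tolerant cells, open points for SK-216, and bars for mean ± SD of 3 arrays. MX1, IFIT1 and TNFSF10 are lower with SK-216 in H1975, SCD and HMGCS1 are higher with SK-216 in PC-9, and MKI67 changes by 0.04 and -0.04.

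Both lines raised SCD, at 0.83 ± 0.16 in H1975 and 2.32 ± 0.16 in PC-9, TRIB3 at 1.38 ± 0.18 and 0.96 ± 0.18, ACAT2 at 0.54 ± 0.15 and 1.46 ± 0.15, SQLE at 0.68 ± 0.16 and 1.20 ± 0.16, and UPP1, uridine phosphorylase, at 1.31 ± 0.12 and 0.61 ± 0.12. Both lowered SNAI2, at -0.67 ± 0.11 and -0.58 ± 0.11, and TNFAIP2 at -0.89 ± 0.10 and -0.43 ± 0.10. The calls of ACAT2 and SQLE in H1975 and of TRIB3, UPP1, SNAI2 and TNFAIP2 in PC-9 ended in 6, 2, 3, 2, 1 and 11 of the 12 fits that left out 1 array (highest adjusted p = 0.199, 0.0681, 0.111, 0.0849, 0.0849 and 0.294). In all, 21 probe sets rose in both lines, against 1.15 for independent lists (Fisher's exact test, p = 5.08e-21), and 3 fell in both, against 0.353 (p = 0.00478). Genes are not independent replicates, so these p-values describe the lists. The number called in the same direction, 24, was 4 without the variance trend, 0 at a log2 change of at least 1, 11 and 15 without PC-9 SK-216 arrays 2 and 3, and 15 without PC-9 tolerant array 3. Over all 21448 probe sets the changes of the lines correlated at r = 0.0293 and rho = 0.0171.

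The change by SK-216 differed between the lines for 304 probe sets, 233 with a more positive value in PC-9 and 71 with a more negative one. Without the variance trend 99 passed, and with quantile normalization 199 were more positive and 107 more negative. The interferon list differed by a mean of 1.05 (PC-9 minus H1975; camera adjusted p = 2.8e-36), and 22 of its 43 genes passed the test of the difference, 36 adjusted over the list alone. TNFSF10 differed by 3.94 ± 0.27 and STEAP4 by 2.83 ± 0.20, and in the other direction ANGPTL4 by -2.95 ± 0.30 and LBH by -1.99 ± 0.26. PDZK1IP1, a membrane-associated protein, fell in H1975 at -1.88 ± 0.13 and rose in PC-9 at 0.56 ± 0.13, a difference of 2.44 ± 0.18, and the PC-9 call ended in 6 of the 12 fits that left out 1 array (highest adjusted p = 0.287). The cholesterol list differed by 0.62 (camera adjusted p = 2.62e-11), the G2/M list by 0.25 (1.62e-05) and antigen presentation by 0.40 (2.16e-05). These 4 of 16 lists also passed with an estimated correlation.

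**Figure D3:**
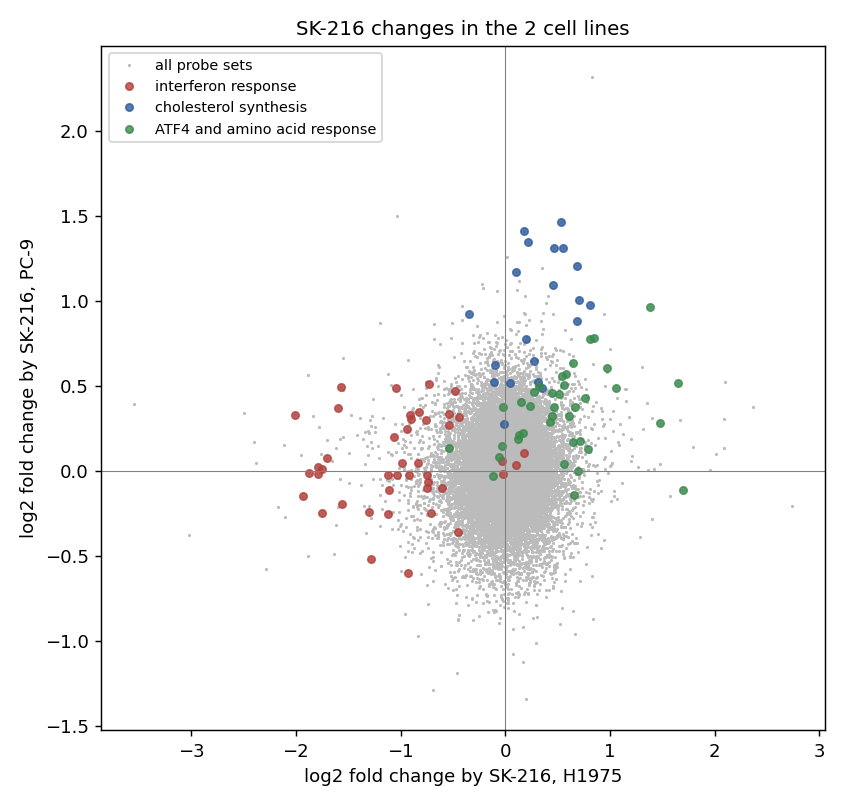
Log2 fold change by SK-216 in H1975 (x axis) and PC-9 (y axis) for all probe sets (grey) and 3 lists (colours). Interferon genes spread to the left and to either side of 0 on the y axis, with medians of -0.93 and 0.02, and cholesterol genes lie above 0 on the y axis and on either side of 0 on the x axis, with medians of 0.30 and 0.95.

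Without SK-216, tolerant PC-9 and H1975 cells differed widely. All 23 measured epithelial markers were higher in PC-9, 23 adjusted over the list alone, with a median difference of 3.39 (camera adjusted p = 2.85e-16), and ESRP1, an epithelial splicing factor, was higher by 10.45 ± 0.21. Of 26 NRF2 targets 23 were higher in PC-9 (camera adjusted p = 5.17e-14), and the aldo-keto reductases AKR1C2 and AKR1C1, near-identical paralogs, were higher by 10.82 ± 0.21 and 10.61 ± 0.13. CYP4F11, a cytochrome P450, was higher in PC-9 by 10.73 ± 0.17 and VGLL1 by 10.21 ± 0.19. Interferon response genes were lower in PC-9 for 39 of 43 members (median -2.40, camera adjusted p = 5.17e-21), and IFI27, an interferon-induced gene, differed by -9.82 ± 0.18. H1975 also had more VCAN, a matrix proteoglycan, at -10.16 ± 0.18 (PC-9 minus H1975), IL7R, the interleukin 7 receptor, at -10.01 ± 0.17, CCL2, a chemokine, at -9.71 ± 0.17, and XAGE1B, a cancer-testis antigen with near-identical copies, at -11.23 ± 0.21. In the line with less, ESRP1, AKR1C2, CYP4F11, VGLL1, IFI27, VCAN, IL7R, CCL2 and XAGE1B lay within the range of olfactory receptor probe sets. VIM differed by -6.39 ± 0.14 and CDH1 by 4.37 ± 0.13. In all, 9433 probe sets passed, 4573 higher in PC-9 and 4860 higher in H1975. Of 17 lists past camera 6 passed with an estimated correlation, the others of the 6 being hypoxia, G1/S and DNA replication, and ribosome biogenesis, all lower in PC-9. These differences are between 1 line and 1 line, and cannot be assigned to the tolerant state.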

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

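The tests of starting level, of the later collection and of the source name were chosen after what they concern had been seen, and the tests of single arrays, scaling and splits before. The SK-216 change differed between the lines, by the test of the difference itself, for 304 probe sets, and without the variance trend for 99. Among 100 of the 200 ways to split the arrays of both lines, with arms of either orientation, 1 gave as many, the real one, and the highest other count was 279, from the real H1975 split with the PC-9 arrays split otherwise. Such splits keep the H1975 change, so the rank of the real split does not test whether the difference between the lines exceeds chance. Where neither line kept its real split the highest count was 1.

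Lists whose change differed are given as mean difference (PC-9 minus H1975, relative to all probe sets), with the adjusted p with an estimated correlation in parentheses: AhR targets at -0.42 (0.0886), squamous and neuroendocrine markers at -0.31 (0.213), hypoxia response at -0.31 (0.0854), ATF4 and amino acid response at -0.22 (0.213), ribosomal proteins at 0.16 (0.524), lysosome and autophagy at 0.18 (0.22), replication-dependent histones at 0.19 (0.433), extracellular matrix at 0.19 (0.135), fatty acid synthesis at 0.23 (0.195), G2/M and mitosis at 0.25 (0.0339), oxidative phosphorylation at 0.31 (0.265), NF-kB and cytokines at 0.33 (0.0549), metallothioneins and zinc at 0.38 (0.22), antigen presentation at 0.40 (0.0339), cholesterol synthesis at 0.62 (0.00613) and interferon response at 1.05 (0.000296). Fits that left out 1 array ended the calls of extracellular matrix in 4 of 12, squamous and neuroendocrine markers in 3, fatty acid synthesis in 3, histones in 2, AhR targets in 1 and ribosomal proteins in 1. Of the 100 splits 5 gave as many as the 16 lists, the real one included, and the highest other count was 19, from the real H1975 split with the PC-9 arrays split otherwise. Where neither line kept its real split the highest count was 11. Each split that reached 16 thus held the real SK-216 grouping of at least 1 line. Their share is therefore not a rate under chance, and for the number of lists these splits neither exclude chance nor argue for it.

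Genes named in the text that passed the test of the difference with a negative value, less positive in PC-9, had log2 differences of ANGPTL4 -2.95, LBH -1.99, IGFBP3 -1.95, RCAN1 -1.95, AGR2 -1.91, SLC7A11 -1.81, STK32A -1.79, PLIN2 -1.72, CYP1A1 -1.68, ATP6V0D2 -1.65, DUSP15 -1.58, FOSL1 -1.37, ATF3 -1.20, ESRP1 -1.15, TIPARP -1.11, CCND1 -0.76, HSPA4L -0.72, SLC3A2 -0.70, UPP1 -0.70, IER3 -0.69, STC2 -0.66, SLC2A1 -0.65, CYP1B1 -0.52 and HSPA5 -0.42. Positive differences that passed, of at least 1.2, were MVD 1.23, MFAP5 1.32, COL8A1 1.34, SCD 1.49, CXCL1 1.54, SMAD6 1.55, SERPINB4 1.71, CDH1 1.74, IFIT3 1.76, MX1 1.77, SAA1 1.81, NFE2 1.83, SERPINB3 1.96, BMP4 2.26, IFIT1 2.34, S100A9 2.42, PDZK1IP1 2.44, MGP 2.57, ACP3 2.64, STEAP4 2.83 and TNFSF10 3.94. Smaller positive differences that passed were MT2A 0.44, HSPB1 0.50, SPARC 0.55, RPS15 0.56, HSPA1A 0.58, ATP5MC1 0.59, TMEM97 0.66, PLAU 0.72, FADS2 0.72, HMGCS1 0.76, SAMD9L 0.77, S100A10 0.78, CYP51A1 0.85, HLA-E 0.85, PFKL 0.86, MT1H 0.92, ACAT2 0.93, AKR1C3 0.93, BID 0.95, CCL2 0.97, E2F8 0.98, FN1 1.04, FDPS 1.06, IDI1 1.13 and IFI27 1.17. Of these 70 differences 42 kept their calls in all 12 fits that left out 1 array and 28 did not. Calls ended in 10 of these fits for ESRP1 and PLAU, in 9 for CCL2, ATP5MC1, MFAP5, SMAD6 and HSPB1, in 8 for MT2A, SAMD9L and HSPA1A, and in 7 for AKR1C3, STK32A and UPP1. They ended in 5 for HSPA5, MVD, RPS15, BID and MT1H, in 4 for ACAT2, in 3 for CYP1B1, in 2 for PFKL, FADS2, CYP1A1, DUSP15, TMEM97 and IFI27, and in 1 for HLA-E and HSPA4L. At least 1 of the 4 group means lay at or under the olfactory receptor 95th percentile for ANGPTL4, AGR2, STK32A, PLIN2, ATP6V0D2, ESRP1, CCL2, IFI27, MFAP5, SMAD6, SERPINB4, NFE2, SERPINB3, IFIT1, MGP and ACP3, and the effect of background on these sizes was not tested.

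The first pattern is the fall of interferon response genes in H1975 without one in PC-9, where many of them started low. A floor in PC-9 would leave brighter members free to fall, yet the 23 members that lay at least 2 log2 units above the olfactory receptor 95th percentile in tolerant PC-9 cells differed by a median of 1.00 (quartiles 0.76 and 1.23), all 23 in the same direction. That argues against a floor of the array for these 23 members, and other effects of a low starting level were not tested. A single array does not account for the pattern, since the list's difference was 1.00 at the lowest when each of the 12 arrays was left out. Whether 48 h of further culture rather than SK-216 lowered these genes cannot be told apart, because 0 arrays of tolerant cells were collected at the later time without SK-216. A response to SK-216 that depends on the cell line stays open as a hypothesis.

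The second pattern is the larger rise of cholesterol synthesis genes in PC-9. A higher starting level in H1975 could compress the change there, but the 13 members that started lower in H1975 also differed, by a median of 0.37 (quartiles 0.21 and 0.76). That is less than the median of 0.61 over all 20. The 13 were chosen by tolerant values that also enter the difference, which by itself can lower it. Whether starting level accounts for part of the larger rise is therefore not decided. The scaling does not remove the larger rise in PC-9, with a list difference of 0.55 at the lowest under quantile normalization or median centring against 0.62. Added time in culture and the cell line itself stay open, untested.

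The third pattern is the source name that calls the SK-216 cells naive before SK-216. If they had never met osimertinib, the SK-216 change would hold the loss of osimertinib as well. No array of naive cells is among the 12 (0 arrays), so the 2 readings cannot be told apart. The G2/M list had a mean shift of 0.00 in H1975 and 0.25 in PC-9, and ERK pathway output 0.31 and 0.17.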

How the results depend on the processing

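Quantities listed here are numbers of calls, and 3 settings were chosen after the data were examined: the filter at olfactory receptor levels, the removal of the most distant array of each line, and the removal of unnamed probe sets. For the second, the pair of arrays was left out first and its distance (0.323 and 0.331 root mean square log2 units, against 0.282 at the lowest) was measured afterwards. Without the variance trend the calls were 448 in H1975, 18 in PC-9, 99 for the difference and 4 shared in direction, and the cause was not tested. By construction stricter thresholds gave fewer: with a log2 change of at least 1 there were 154, 21, 147, 0 shared and 4548 between lines, and at an adjusted p below 0.01 there were 422, 33, 136 and 10 shared, with 11 lists in H1975. With an estimated correlation 9, 8 and 4 lists passed in H1975, PC-9 and the difference, and 13 in H1975 without genes of several lists. The replicate block within each line gave 673 in H1975, 58 in PC-9 and 14 shared, and over both lines 732, 73 and 18. Arrays of 1 number did not deviate together (r from -0.0912 to 0.0295), and not every array correlated best with its own number, so the numbers are not taken to pair the arrays. Without the most distant array of each line, with fewer arrays, PC-9 had 61 calls and 14 were shared.

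Leaving out each array gave 545 to 918 calls in H1975, 30 to 104 in PC-9, 220 to 335 for the difference, 8777 to 9452 between lines and 11 to 25 shared. The PC-9 count moved by over 1.5 times without SK-216 arrays 1, 2 and 3 (60, 30 and 59) and tolerant array 3 (46). The shared count did so without PC-9 SK-216 arrays 2 and 3 (11 and 15) and PC-9 tolerant array 3 (15). Lists numbered 15 to 21, 15 to 17 and 13 to 18. Quantile normalization moved the share of higher calls from 84.2% to 73.9% in PC-9 and from 76.6% to 65.0% for the difference, and 69 and 306 passed. No called value changed its direction. Of named gene values outside the leave-outs 7099 kept their side of the threshold, 476 fell short and 56 newly passed. For lists past the test the numbers were 669 and 121. The 7099 include values that were not calls to begin with. Of the calls of named genes, 25 of 106 in H1975 and 29 of 47 in PC-9 ended in at least 1 fit that left out an array. Between the lines 0 of 10 did. The pseudocount alternative, which needs linear values, was not run. Leaving out probe sets at olfactory receptor levels, with fewer tests, gave 937 calls in H1975, with 763 of the 814 among them, and 128 in PC-9, with 93 of the 95. What low signal hides was not tested.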

Other observations

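The tests of gene families were chosen after the data were examined, and those of splits before. Transfer RNA synthetases, which charge transfer RNAs with amino acids, split by compartment. In H1975 the 16 cytosolic synthetase genes had a median change of 0.30 and 7 rose, while the 15 mitochondrial ones had a median of -0.10 and 0 rose (limma; camera adjusted p over 14 families 2.05e-07 and 0.743; 0.0108 and 0.809 with an estimated correlation). In PC-9 the cytosolic median was 0.22, with 2 rises (camera adjusted p = 1.09e-05; 0.0272 with an estimated correlation), and the mitochondrial one was 0.01, which turned to -0.04 with quantile normalization. That both kinds respond differently in H1975 is a hypothesis taken from these same values, so the difference of the medians, 0.41, describes it and does not test it. The ATF4 list holds 5 of the cytosolic genes and 0 of the mitochondrial ones, so the result overlaps with that list.

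Among the other families sorted by symbol, S100 genes held 5 falls and 0 rises among 21 in H1975 (camera adjusted p = 0.000121; adjusted p = 0.0673 with an estimated correlation). Proteasome subunits in PC-9 had a median of 0.18 with 0 calls (limma adjusted over all genes), and adjusted p = 0.253 with an estimated correlation. Olfactory receptors, 349 probe sets near the floor, had medians of 0.06 in H1975 and -0.08 in PC-9, and differed by -0.14 (camera adjusted p = 0.00525; 0.0396 with an estimated correlation). With quantile normalization these were 0.03, -0.04 and -0.07, in the same directions. Arrays of PC-9 with SK-216 had lower quartiles of 4.28, 4.30 and 4.32 and tolerant arrays 4.35, 4.35 and 4.37, so small shared shifts of bright or dim lists in PC-9 lie within a range that scaling can move. For the numbers of calls, 3 arrays against 3 make 10 splits, too few for a share below 0.05. The real splits gave 814 genes in H1975, 95 in PC-9 and 9433 between lines, and the highest others gave 1, 0 and 0. For lists the real splits gave 21 in H1975 and 17 in PC-9, and the highest others 9 and 8. In each of these 5 results 1 split, the real one, gave as many. Of 100 splits of both lines 1, the real one, gave as many as the 24 genes called in the same direction, with 0 as the highest other. Splits of a single line called at most 1 gene in H1975 and 0 in PC-9, so few shared genes were possible in the other splits, and the comparison does not test whether sharing between the lines exceeds chance.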
